A study of Caenorhabditis elegans with 2 samples.

How the data were processed

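The series holds ChIP-seq of the nuclear hormone receptor NHR-12 carrying a GFP tag, from whole Caenorhabditis elegans at the L2 larval stage. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) enriches DNA that lay near the tagged protein and finds the enriched intervals as peaks. The strain carries an integrated transgene with tagged nhr-12 and, per the labels, the unc-119(ed3) mutation. Per the labels, the 2 samples are biological replicates of 1 group, male and female animals were pooled, and fragments were selected between 150 and 350 bp. No second condition is part of the design, so no difference between groups was tested.

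The authors deposited peak lists, not reads. Per the file headers and accompanying notes, a relaxed list was called for each replicate and for the pooled replicates, each against a control, and a shorter list holds the pooled peaks that passed a threshold on the irreproducible discovery rate (IDR), a measure of how far replicates rank peaks alike. The peak caller, its settings, the aligner and the IDR threshold are not given in the sources used here. The deposited signal value of each peak was given by the caller against a control, on a scale that differs between lists, and is used here only to rank, filter and describe peaks. The deposited −log10 q-value is the caller's own and was at its highest, 2.66, in 227 of the 228 thresholded peaks, so it was not used for ranking. Read depth is unknown, since the lists carry no counts, and no interval that needs depth is given. Control coverage was not analysed here.

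Lists on the ce11 build were used with positions as deposited and counted from 1. Genes came from Ensembl release 115 of WBcel235, which is the same assembly, and mitochondrial gene symbols from the RefSeq gene table. Lists on ce10 entered only counts, signal values and the overlap of the replicates, and no position was converted between builds.

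Chromosome counts were set against 10000 random draws in proportion to length. The share of summits within 500 bp of a gene 5' end was set against 10000 random placements of each summit on its own chromosome (permutation test, two-sided, smallest p 0.0001) and, by Fisher's exact test (two-sided), against the pooled relaxed peaks that overlap no thresholded peak. The median signed distance has a bootstrap interval (95%, 2000 draws over peaks). The strongest 228 peaks of each replicate were overlapped by at least 1 bp and compared with 1000 shuffles within chromosomes (smallest p 0.001). Spearman correlations are across peaks, which are not independent replicates, with 1000 bootstrap draws. A gene was called bound when its 5' end was the nearest to a nuclear summit and within 1000 bp. Fisher's exact test compared bound genes in 24 lists (17 families, pathways and complexes, and 7 sets of cell type markers) and in 11 gene biotypes with all other nuclear genes. The lists of proteins were tested among protein-coding genes, assigned on their own, and microRNAs and biotypes among all annotated genes. Motif presence within 50 bp of the summit was compared by Fisher's exact test for 18 motifs and for all 6-mers. Benjamini-Hochberg adjustment was applied within each family, at 0.05. Exact (Clopper-Pearson) 95% intervals are given for shares of genes, and cover sampling of genes only.

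The lists, motifs, tests and most alternatives were fixed before the data were examined. The rule for named genes was the gene assigned to each of the 25 strongest thresholded peaks, up to 4 bound members of each list, and nhr-12 and unc-119 whatever their values. Because the 25 strongest peaks were all mitochondrial, genes at the 25 strongest nuclear peaks, and RNA genes, were named as well, chosen after their values were seen. Alternatives were other distances, protein-coding genes only, the upper 50% of peaks by signal, each replicate alone, other overlap rules, other backgrounds and motif references matched in strata of 5% GC content. Added after the data were seen were nuclear peaks only, the ce10 replicate lists, removal of peaks at 3 loci with wide peaks, removal of ncRNA and piRNA genes, and combinations of these with planned choices. Also added were motif references matched on GC content alone or on nearness to 5' ends alone, 1 peak per interval in the correlation, and 1000 random placements of the nuclear peaks as the reference for 23 lists of proteins and 11 biotypes. The annotation class of nuclear summits, the contrast of X with autosomes and the nearness to tRNA genes were also chosen after the data were seen. The 3 loci with wide peaks were taken as 5000 bp around F14E5.8, pie-1 and tbb-2, genes picked because wide peaks lay there.

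Gene lists, biotypes, nearness to 5' ends, motifs, 6-mers and the overlap of replicates were tested on simulated data, and the other statistics were not. Among 24 lists, the list given 10 bound members was the only list called, and none was called for random peaks. Of 18 motifs, the motif planted in 25% of windows was the only motif called. Of 2080 6-mers, the 6-mer planted in 10% of windows was the only one called. Test and reference windows were both drawn at random from the genome, so calls that follow from a difference in GC content were not simulated. For random peaks, 33.2% lay near a 5' end against 30.4% of placements (permutation p = 0.39). Planted snRNA genes were called among biotypes, but random peaks also gave calls for protein-coding (odds ratio 1.75) and piRNA genes (odds ratio 0.303), so Fisher's exact test of biotypes can make calls at random positions, and random placement was added for that reason. A planted overlap of 50% was measured as 50%. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.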

Results

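Enrichment of DNA with GFP-tagged NHR-12 in L2 larvae was described by 228 peaks that passed the submitters' IDR threshold. NHR-12 belongs to the large nuclear hormone receptor family of C. elegans. The list was drawn from 29431 pooled relaxed peaks, and each of the 2 replicates had 30000 relaxed peaks. No peak interval was identical in the replicate lists, but the most frequent width was 340 bp in replicate 1 and 316 bp in replicate 2. Peaks of these widths could not share an interval, so this says nothing on replicate agreement. Read depth is unknown, and signal values are the authors' own, without error per peak.

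The mitochondrial genome held 29 of the 228 peaks, against 0.0314 expected by its length of 13794 bp (permutation p = 0.0001, adjusted p = 0.0007). Each summit counts as a peak, and the 228 peaks lay in 216 distinct intervals, 197 nuclear and 19 mitochondrial, so mitochondrial peaks that share an interval are not independent in that test. All 25 strongest peaks were mitochondrial, and the first nuclear peak ranked 27. The strongest summit, with signal value 3520, lay in CYTB (WBGene00000829, M: 4504 to 5621), which encodes cytochrome b. Peaks over ND5 (WBGene00010967, M: 11691 to 13272), a subunit of respiratory complex I, had summits of 1805 and 1387, and the next summit, in ND2, had 911.4. By nearest 5' end, the 25 strongest peaks were assigned to 18 mitochondrial genes, namely 9 protein-coding, 7 tRNA and 2 rRNA genes, at most 768 bp away. The protein-coding genes were CYTB, ND2, COX3, ND3, ATP6, COX2, COX1, ND5 and ND4. Mitochondrial signal values had a median of 471.5 (77.4 to 3520) and nuclear values a median of 46.6 (37.2 to 170.9).

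**Figure D1:**
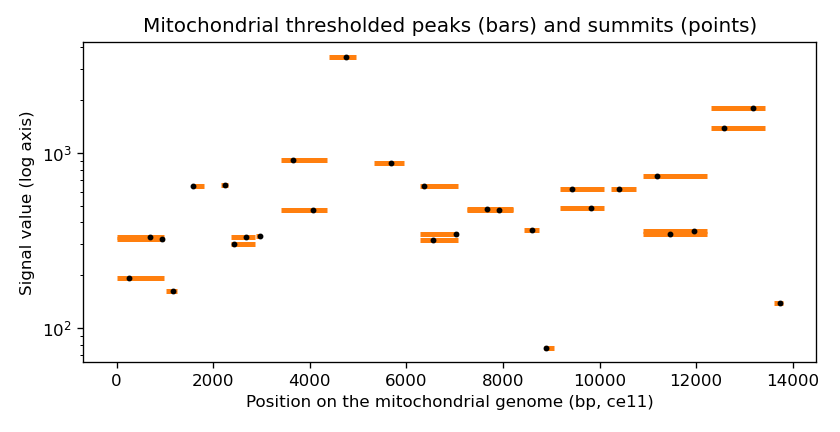
Signal value (log axis) of the 29 mitochondrial thresholded peaks against position in bp on ce11; bars are peak intervals and points are summits. The strongest summit, at 3520, lies in CYTB, and the weakest has 77.4.

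Among chromosomes, V and IV held fewer peaks than their length would give and III held more. Chromosome V had 19 peaks against 47.6 expected (adjusted permutation p = 0.0007), IV had 22 against 39.8 (adjusted p = 0.0044) and III had 43 against 31.3 (adjusted p = 0.044). Chromosomes I, II and X, with 42, 31 and 42 peaks, did not pass the permutation test. With the 199 nuclear peaks alone, chromosome I, with 42 peaks against 29.9 expected, passed as well (adjusted permutation p = 0.031).

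The strongest nuclear peak, at 170.9, lay in intergenic DNA 275 bp upstream of rpl-3 (WBGene00004414; peak III: 3867491 to 3867646), which encodes a protein of the large ribosomal subunit. Other strong peaks lay upstream of cdc-48.1 (108.1, II: 10563533 to 10563613), an AAA ATPase that extracts ubiquitinated proteins, and of cox-5A (103.2, III: 12905043 to 12905362), a cytochrome c oxidase subunit. Peaks near rpl-15 (94.5), eif-3.C (93.4, a translation initiation factor subunit) and sec-61.G (90.2, a subunit of the protein translocation channel of the endoplasmic reticulum) were also upstream of the gene. The nuclear peaks ranked 5 and 6 were upstream of F36A2.7 (107.6) and Y17G9B.5 (107.0), and those ranked 9 and 15 were near puf-9 (99.4) and scpr-1 (92.7). At nspc-17 the value was 92.8, at eelo-2 84.0, at hsr-9 82.8, at ints-4 82.0, at rps-1 81.3 and at tasp-1 80.1. A group of peaks with values up to 139.9 lay in and beside F14E5.8 on chromosome II (8418826 to 8421640), and another, at 95.7, lay 670 bp upstream of pie-1 (III: 12425785 to 12426878), a germline gene. Peaks at both places were wider than the 320 bp that 189 of the 199 nuclear peaks had. Of the 25 strongest nuclear peaks, those nearest to Y48G10A.3 (1497 bp upstream), ZK899.10 (1836 bp upstream), F22H10.2 (2631 bp downstream of its 5' end, in intergenic DNA) and the tRNA gene WBGene00014538 (1561 bp upstream) had no gene 5' end within 1000 bp. The remaining peak of the 25, on X, lay 765 bp upstream of the snoRNA gene T27A8.8.

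Thresholded peaks lay close to gene 5' ends. A summit was within 500 bp of a 5' end for 167 of 228 peaks (73.2%, exact 95% interval 67.0% to 78.9%), against 35.6% of random placements (permutation p = 0.0001, the smallest the draws can give). Of the 29176 remaining relaxed peaks, 35.7% were that close (odds ratio 4.92, Fisher's exact p = 3.1e-30). These relaxed peaks were all nuclear, while the 228 peaks and their random placements include mitochondrial ones. For the 199 nuclear peaks the share was 71.4%, against 28.0% of random placements (permutation p = 0.0001). Against the relaxed peaks their odds ratio was 4.48 (Fisher's exact p = 4.3e-24). Over all 228 peaks, summits lay upstream, with a median signed distance of -98 bp (95% interval -161 to -60.5 bp). Counting only protein-coding genes gave a median of -178.5 bp. Of the 199 nuclear summits, 133 (66.8%) were intergenic against 33.6% by random placement, and 5 (2.51%) were in coding exons against 24.6% (adjusted permutation p = 0.00015 for each). Introns of protein-coding genes held 27 summits (13.6% against 33.9%), 5' UTRs held 9 (4.52% against 1.41%, adjusted permutation p = 0.0022), 3' UTRs held 5 (2.51% against 3.46%, adjusted permutation p = 0.56), and exons of non-coding genes or pseudogenes held 20 (10.1% against 3.01%, adjusted p = 0.00015).

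**Figure D2:**
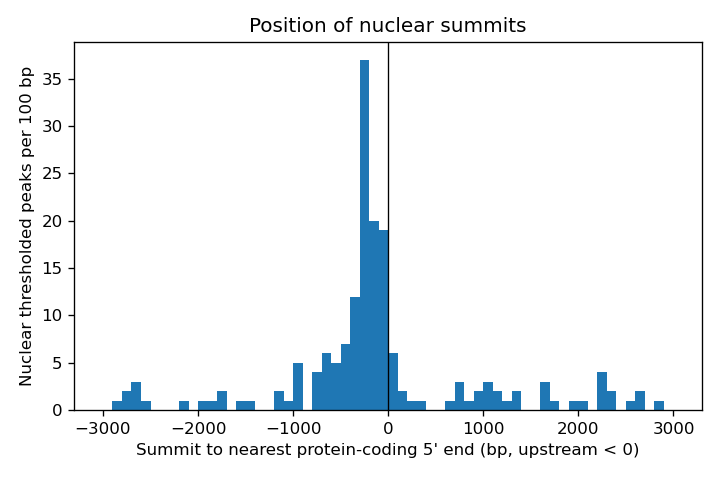
Number of nuclear thresholded peaks per 100 bp against the distance in bp from the summit to the nearest protein-coding 5' end, negative upstream; 173 of the 199 peaks lie within 3000 bp and are drawn. The tallest bars lie just upstream of 0, and 76 peaks are within 300 bp upstream.

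Genes of the translation machinery and of the respiratory chain were called bound more often than other protein-coding genes. No sample without the tagged protein was analysed here, so whether peaks are specific to NHR-12 was not tested. Of 19973 nuclear protein-coding genes, 129 were bound. Cytosolic ribosomal protein genes had 7 of 82 bound (8.54%, exact 95% interval 3.50% to 16.8%) against 0.613% of other genes (odds ratio 15.1, adjusted Fisher's exact p = 2.4e-05). The strongest were rpl-3 (170.9), rpl-15 (94.5), rps-1 (81.3) and rpl-12 (76.1). Translation initiation and elongation factors had 5 of 38 bound (13.2%, 4.41% to 28.1%; odds ratio 24.2, adjusted Fisher's exact p = 5.3e-05), led by eif-3.C (93.4), iff-2 (64.7), eif-3.J (48.9) and eef-1B.1 (42.5). Nuclear genes of the respiratory chain and ATP synthase had 3 of 38 bound (7.89%, 1.66% to 21.4%; odds ratio 13.5, adjusted Fisher's exact p = 0.015), namely cox-5A (103.2), cox-5B (57.2) and cox-6A (42.9). With replicate 1 alone, translation factors had 2 of 38 bound and were no longer called (odds ratio 9.02, adjusted Fisher's exact p = 0.11). The respiratory chain call was lost with 5' ends within 500 bp (odds ratio 10.8, adjusted Fisher's exact p = 0.13), and with replicate 2 alone its odds ratio was 25.4 (adjusted Fisher's exact p = 4.2e-05).

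The other 21 lists did not pass. Nuclear hormone receptors had 2 of 274 bound (0.730% against 0.645%, adjusted Fisher's exact p = 1), nhr-47 (44.9) and nhr-48 (37.2). With replicate 1 alone 0 were bound, and with replicate 2 alone 4 were (1.46%, odds ratio 2.44, adjusted Fisher's exact p = 0.54). Fatty acid metabolism had cpt-2 (42.6), a carnitine palmitoyltransferase, as the bound member of 76. When every gene with a 5' end within 1000 bp of a summit was counted, in place of the nearest, heat shock proteins passed, with 4 of 22 bound (odds ratio 24.3, adjusted Fisher's exact p = 0.00037); by nearest 5' end they had hsp-3 (38.5). Histones had his-37 (73.2), the proteasome rpn-3 (38.2), basic helix-loop-helix genes hlh-11 (41.3) and microRNAs mir-5549 (70.0). Among 7 sets of cell type markers, 6 had 0 bound members: intestine, hypodermis and seam, body wall muscle, pan-neuronal, ciliated neuron and germline. The pharynx set had pqn-27 (38.8) and pqn-70 (38.5) of 91 (adjusted Fisher's exact p = 0.64). Cytochrome P450s, UDP-glucuronosyltransferases, glutathione S-transferases, cuticle collagens, vacuolar ATPase, ceh homeobox genes and heterochronic genes also had 0 bound members. Most of these sets were small, so an absence of calls does not exclude binding of a few members.

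Genes for small structural RNAs were called bound more often than other genes. Of 129 snRNA genes, 4 were bound (3.10%, odds ratio 9.81, adjusted Fisher's exact p = 0.0034), among them sls-2.1 (56.4) and sls-2.8 (52.1), which encode SL2 spliced leader RNAs used in trans-splicing. Of 346 snoRNA genes 5 were bound (1.45%, odds ratio 4.50, adjusted Fisher's exact p = 0.014), and of 612 tRNA genes 7 (1.14%, odds ratio 3.58, adjusted Fisher's exact p = 0.013). All 7 bound tRNA genes lay on X, which has 276 of the 612. The peak at rpr-1, the RNA of ribonuclease P, had a value of 71.2. Protein-coding genes had 102 of 19973 bound in this assignment (odds ratio 2.55, adjusted Fisher's exact p = 6.9e-08). Against other genes, fewer piRNA genes, 4 of 15363 (odds ratio 0.0538, adjusted Fisher's exact p = 2.4e-20), and pseudogenes, 1 of 2128 (odds ratio 0.135, adjusted Fisher's exact p = 0.020), were bound. With replicate 1 alone 0 piRNA genes were bound (odds ratio 0.00652, with 0.5 added to each count). Neither biotype passed against random placement of the nuclear peaks, which gave 7.34 piRNA genes and 5.40 pseudogenes (adjusted permutation p = 0.36 and 0.13). Protein-coding, snRNA, snoRNA and tRNA genes did pass there, against 60.6, 0.210, 0.904 and 1.11 by placement (largest adjusted permutation p = 0.0044), as did ncRNA genes, with 31 bound against 16.6. Random placement does not keep the nearness of peaks to 5' ends (71.4% of nuclear summits within 500 bp, against 28.0% when placed). A biotype can thus pass from that nearness alone, and a low count can fail to pass. This reference therefore does not decide whether peaks prefer or avoid a biotype. Without ncRNA and piRNA genes, the odds ratio of protein-coding genes was 0.941 (adjusted Fisher's exact p = 1) and snoRNA genes no longer passed (adjusted p = 0.13). In the upper 50% of peaks, 1 of 612 tRNA genes was bound (odds ratio 1.20, adjusted Fisher's exact p = 0.78), and the calls of snoRNA genes (2.14, adjusted p = 0.59) and pseudogenes (0.334, adjusted p = 0.59) were lost as well. The latter calls were also lost with replicate 2 alone (odds ratio 2.74, adjusted Fisher's exact p = 0.22, for snoRNA genes and 0.572, adjusted p = 0.60, for pseudogenes). The snoRNA call did not hold with genes at relaxed peaks as the background (odds ratio 3.08, adjusted Fisher's exact p = 0.051), and with replicate 1 alone 11 of 346 snoRNA genes were bound (odds ratio 10.5).

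The nuclear receptor element AGGTCA was not more frequent at the peaks. It lay within 50 bp of 3 of 228 summits (1.32%), against 1.79% of the relaxed peaks (odds ratio 0.731, adjusted Fisher's exact p = 0.85). With replicate 1 alone it was at 1 of 228 summits (odds ratio 0.242, adjusted Fisher's exact p = 0.26). The related sequences GGGTCA (2.19% against 0.991%, adjusted Fisher's exact p = 0.12) and AGTCCA (3.07% against 1.68%, adjusted p = 0.15) did not pass either. AGTTCA was at 3.07% against 6.75% (odds ratio 0.438, adjusted Fisher's exact p = 0.052), and this lower frequency passed within 25 bp (odds ratio 0.131, adjusted p = 0.028), within 100 bp (0.560, adjusted p = 0.032) and with replicate 1 alone (0.247, adjusted p = 0.0024). It did not pass with replicate 2 alone (odds ratio 0.569, adjusted Fisher's exact p = 0.22), against flanking windows (0.544, adjusted p = 0.36) or against relaxed peaks matched on GC content and 5' ends (0.599, adjusted p = 0.64). Of the 18 motifs, 6 passed. GAGAGA was at 18.4% of summits against 4.79% (odds ratio 4.48), GGGCGG at 4.82% against 0.967% and CACGTG at 3.51% against 0.997%. TGATAA (2.63% against 11.2%), TTTCAG (7.02% against 20.6%) and AAAAAA (27.2% against 58.9%) were less frequent. With replicate 1 alone the odds ratio of GAGAGA was 7.66, that of TTTCAG 0.158 against 0.290 and that of AAAAAA 0.162 against 0.261, and with replicate 2 alone that of AAAAAA was 0.401. The CACGTG call (odds ratio 3.61) was lost with replicate 2 alone (1.31, adjusted Fisher's exact p = 0.65), in the upper 50% of peaks (1.77, adjusted p = 0.52) and against flanking windows (1.46, adjusted p = 0.64). The TGATAA call (odds ratio 0.214) was lost with replicate 2 alone (0.519, adjusted Fisher's exact p = 0.053). Nuclear summit windows had a median GC content of 46.5% and relaxed windows 27.7%. Against relaxed peaks matched on GC content and nearness to 5' ends none of these 6 motifs passed, with 1813 reference windows in place of 29176. The odds ratios of GAGAGA (1.20, adjusted Fisher's exact p = 0.68), CACGTG (1.14), GGGCGG (0.907) and AAAAAA (0.944) lay near 1. For nuclear summits alone they were 1.37, 1.31, 1.05 and 0.760 in that order, and none passed. Those of TGATAA (0.435, unadjusted Fisher's exact p = 0.044, adjusted p = 0.38) and TTTCAG (0.616, adjusted p = 0.38) kept their direction, so a lower frequency of these is not excluded. TATAAA was the 1 motif that passed there (odds ratio 2.07, adjusted Fisher's exact p = 0.026), and none passed when mitochondrial peaks were also left out. The same matched windows served with and without mitochondrial summits, so the match may not hold for the mitochondrial ones. Of 2080 6-mers, 435 were more frequent and 136 less frequent at the peaks, and GACGCA led, at 18.9% of summits against 1.61% (adjusted Fisher's exact p = 2.5e-28). For nuclear peaks against the reference matched on GC content and 5' ends, 29 were more frequent and 0 less frequent.

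Replicates shared part of their strongest peaks. Of the 228 strongest peaks of replicate 1, 99 (43.4%) overlapped the 228 strongest of replicate 2, against a mean of 9.68% in shuffles (p = 0.001 by shuffling, a permutation test). Among nuclear peaks alone, 75 of 199 (37.7%) overlapped, against 0.150%. The share of overlapping nuclear peaks was 48% for the top 100, 27.2% for the top 500, 23% for the top 1000, 16.4% for the top 5000 and 18.9% for the top 10000. In 20 shuffles each, the mean was 0%, 0.400%, 0.770%, 3.31% and 6.46%. Across the 223 thresholded peaks found in both replicates, signal values correlated with Spearman's rho of 0.521 (95% interval 0.378 to 0.631). Because these peaks passed a threshold on IDR, part of this correlation may follow from their selection. Peaks that share an interval repeat the same replicate values, and with 1 peak per interval rho was 0.437 over 211 peaks. Across 194 nuclear peaks rho was 0.299 (0.148 to 0.428). Pooled signal had a rho of 0.808 with replicate 2 and 0.647 with replicate 1. The pool is made from both replicates, so these are correlations of a whole with its parts and not of replicate agreement. Peaks at hsr-9, his-37, nra-2 and eel-1 had no overlapping peak in replicate 2, and the peak near C56G2.9 had none in replicate 1. Of the 199 nuclear thresholded peaks, 153 ranked within the upper 1000 of both replicates, and the lowest rank in replicate 1 was 29475. A place in the thresholded list thus did not require a high rank in both replicates.

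**Figure D3:**
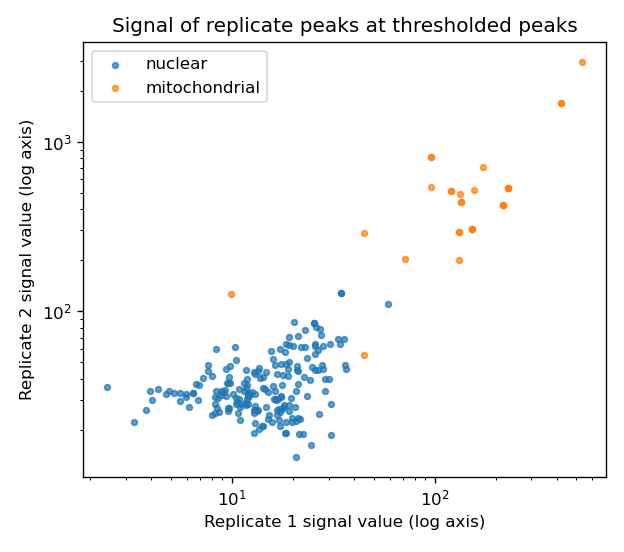
Signal value of the strongest overlapping peak in replicate 2 against replicate 1 (both axes log) for thresholded peaks; 1 point per peak. Mitochondrial peaks extend to 534.2 and 2948, and the 194 nuclear points have a Spearman's rho of 0.299.

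The tagged gene itself carried no peak. Within 5000 bp of nhr-12 (WBGene00003611, V: 10082133 to 10084049) there were 0 peaks in the thresholded list, in the pooled relaxed list and in each replicate, and the nearest relaxed summits were 23445 bp (pooled), 20835 bp (replicate 1) and 18513 bp (replicate 2) away. At unc-119 (WBGene00006843, III: 10902641 to 10908935), mutated in the strain, there were 0 thresholded peaks. The relaxed lists had 7 peaks there in the pool, 6 in replicate 1 and 10 in replicate 2, with best ranks of 4644, 992 and 4804.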

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

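The settings with nuclear peaks alone, without the wide-peak loci or without ncRNA and piRNA genes, with random placement for lists and biotypes, with 1 peak per interval or with motif references matched on 1 property, the ce10 replicate lists, and the tagged gene in each replicate alone, were chosen after the data were seen. The nearness to 5' ends, its contrast with relaxed peaks and the overlap of the replicates kept their direction and passed under each setting run. The number of peaks was 114 in the upper 50% by construction. The median distance was -178.5 bp for protein-coding genes only and -212 bp for these with nuclear peaks. The correlation between replicates was 0.686 in the upper 50% and 0.299 for nuclear peaks. The causes were not tested. Lists called numbered 2 to 4 over the settings, against 3, and the added list was heat shock proteins, with every gene within 1000 bp counted. Biotypes called as enriched numbered 2 in the upper 50%, where fewer peaks were tested, and 2 without ncRNA and piRNA genes, against 4. Without ncRNA and piRNA genes the protein-coding odds ratio reversed to 0.941. That setting removed most of the comparison genes and also reassigned some peaks to other genes. Which of these changes gave the turn was not tested. Motifs called, 6, became 10 for nuclear peaks, 1 against relaxed peaks matched on GC content and 5' ends, where the GGGCGG odds ratio turned to 0.907, and 0 for nuclear peaks matched so. Matched on GC content alone, 1 motif, TATAAA (odds ratio 2.47, adjusted Fisher's exact p = 0.0013), was called, and the odds ratios of GGGCGG (0.910) and AAAAAA (1.04) turned. The reference windows were all nuclear, while the summits included mitochondrial ones. Nuclear summits alone had TATAAA at 9.55%, against 13.6% for all summits. They had AAAAAA at 23.1%, against 27.2% for all summits and 26.3% for the reference. GGGCGG was at 5.53% of nuclear summits, against 4.82% for all summits and 5.28% for the reference. Mitochondrial summits thus raised the values of TATAAA and AAAAAA and lowered that of GGGCGG. The turns of AAAAAA and GGGCGG depend on them. Matched on 5' ends alone, 6 were called. The 6 motif calls thus depend on the GC content of the reference. Against flanking windows, 5 of them were kept, all but CACGTG. There the odds ratio was 4.23 for GAGAGA (adjusted Fisher's exact p = 2.1e-06) and 0.332 for TTTCAG (adjusted p = 0.00029). With each replicate alone, list calls were 2 and 3, biotype calls 4 and 3 and motif calls 9 and 4. The overlap and correlation of replicates and the count of peaks have no value without a replicate. Read depth is unknown, so what it limits was not assessed.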

Other observations

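Peaks on X lay less often near protein-coding 5' ends than those on autosomes, and more often near tRNA genes, in tests chosen after the peaks were seen. Of 42 peaks on X, 15 (35.7%) had a protein-coding 5' end within 1000 bp, against 117 of 157 autosomal peaks (74.5%; odds ratio 0.190, Fisher's exact p = 5.6e-06). Random placement gave 29.0% on X (permutation p = 0.40) and 34.9% on autosomes (permutation p = 0.0001, the smallest possible). Of the X peaks, 9 of 42 (21.4%) had a tRNA 5' end within 1000 bp, against 2.35% of random placements on X (permutation p = 0.0001), and 2 of 157 autosomal peaks did (1.27% against 0.722%, permutation p = 0.63). The shares differed (odds ratio 21.1, Fisher's exact p = 1.6e-05). Because X is richer in tRNA genes, equal enrichment over random placement would put 46.6% of these 11 peaks on X, against the 9 seen (exact binomial p = 0.030). Examples on X are the tRNA genes WBGene00023050, with a peak of 52.7 at 80 bp upstream, and WBGene00023110, with a peak of 49.9 at 22 bp upstream.

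Some 6-mers were more frequent at nuclear summits even against relaxed peaks matched on GC content and nearness to 5' ends, a comparison added after the data were seen. Of 2080 6-mers, 29 were more frequent and 0 less frequent. GACGCA was at 21.6% of nuclear summits against 7.23% (odds ratio 3.54, adjusted Fisher's exact p = 3.6e-06), ATCGCG at 11.1% against 2.04%, CCCTGC at 11.6% against 2.26% and CCTGCG at 12.6% against 2.81%. Read on either strand, GACGCA, CCTGCG and CCCTGC can be overlapping parts of 1 longer sequence, so the 29 are not independent. The joint match reached 1813 reference windows, against 1990 when matched on GC content alone, so some strata ran short. Whether a difference in GC content remained after matching was not tested.

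Of the tests of explanations that follow, those of mitochondrial DNA abundance, a construct, strong enrichment, coincidence and the control library were chosen after the values were seen. Mitochondrial peaks led the list. The AGGTCA element does not account for them, since 0 of 29 mitochondrial summits had it, which allows at most 11.9% (exact 95% limit). Peaks covered 76.9% of the mitochondrial genome in the pooled list, 74.1% in replicate 2 and 54.9% in replicate 1, so an abundance of mitochondrial DNA may be a source of these peaks. The control was used in calling, so why abundance would not cancel stays open, and no biological explanation was tested.

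Nuclear peaks wider than the standard 320 bp of the pooled list lay at F14E5.8, pie-1 and tbb-2. Strong enrichment alone does not account for them. Of the 32 pooled nuclear peaks at least as strong as the median wide peak (73.7), 28 were not wide. The exact 95% limit leaves at most 29.0% wide. That limit is only a guide, because the cut came from the wide peaks and peaks at the same locus are not independent. Repeated sequence does not account for the wide peaks either, since 95.7% of the 31-mers at these loci occur once in the genome. The pie-1 promoter, the tbb-2 3' UTR and the insertion site beside F14E5.8 are parts often used in worm transgene constructs, so DNA of a transgene construct in a library may be a source. This cannot be told apart from other sources here: the 0 wide peaks elsewhere follow from picking the loci where peaks were wide, and replicate 1 had 0 wide peaks. Replicate 2 had 7 wide nuclear peaks (349 to 1218 bp), 0 of them outside these loci. No biological explanation was tested.

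The relaxed peaks left a gap of 64551 bp around nhr-12 in the pooled list, the rank 9 gap by length, and gaps of 61310 and 59624 bp in replicates 1 and 2. Few nuclear protein-coding genes lay in gaps as long, 0.461% in all 3 lists and 0.646% to 1.15% in single lists. The lists are not independent, since the pooled list is made from the replicates. Coincidence is thus disfavoured but not excluded, as the test was chosen after the gap was seen. Reads that could not be placed do not account for it, with 97.9% of its 31-mers found once, nor do few gene 5' ends, whose density was 155.5% of the genome's. Extra copies of the tagged locus in the control library may lower enrichment there, but this cannot be told apart from other causes, because control coverage was not analysed here. No biological explanation was tested.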
